A study of Mus musculus with 8 samples.

How the data were processed

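RNA from mouse embryos was measured on 8 2-colour Agilent arrays of 60-base probes. Each array carried amplified embryo RNA in the Cy3 channel and a common reference RNA in the Cy5 channel, and the dyes were not swapped. Per the labels, embryos were collected from oviducts and uteri on day 4 of pregnancy, from females mated with males of their own genotype, morulae were sorted from blastocysts by eye, about 50 blastocysts were pooled per RNA sample, and the RNA went through 2 rounds of linear amplification. The reference was a pool of RNA from 11 mouse cell lines mixed with RNA from embryonic stem cells of strain 129. The labels gave 4 groups of 2 arrays: wild type blastocysts, Cnr1-null blastocysts, Cnr1-null morulae and Faah-null blastocysts. They did not say whether the 2 pools of a group came from separate animals, so p-values measure the spread between these samples, which may be partly technical. The label identifier of Cnr1-null blastocyst replicate 2 carries the pool number 3.

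The deposited scanner tables hold mean spot intensity and median local background intensity per channel. Per the file headers they were extracted with Agilent Feature Extraction 9.5.1.1, the tool that the submitters' processing notes also name. The tables also hold processed intensity, which per the file headers was spatially detrended, and a log10 ratio of Cy5 over Cy3. The deposited log10 ratio is thus positive where the reference was brighter, and all signed values given here run the other way, embryo over reference. A second deposited table holds log10 values of the authors for 25030 spots. Each of its columns followed the log10 of the processed Cy3 intensity of its own array (r 0.995 to 0.998 across spots, which are not independent replicates) more closely than that of any other array (at most 0.982). Its column medians ran from 2.05 to 2.18. Its scale is log10 and its direction is that of the embryo channel, and the normalization behind it is not given in the sources used here. For the probes named below, 12 results could be computed from it. Their log2 differences between groups were the same as those of the processed embryo over reference ratio. At these probes its group differences are thus those of a ratio against the reference, not of the Cy3 channel alone.

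The probes carry only numbered identifiers and their sequences. The files do not pair them with genes or genome positions, and 0 of the identifiers were found in the gene table of the mouse assembly GRCm38.p6. The gene lists and the named-gene rule chosen before the data were examined, the check of Cnr1 and Faah themselves, and the choice of 1 probe per gene were therefore not run. Each probe was tested on its own. The rule for named items became the 2 probes with the largest rise and the 2 with the largest fall among those past the threshold in each comparison, and likewise among those shared by both mutants, ranked by the smaller of the 2 changes.

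Background was corrected with normexp at an offset of 50, and each array was normalised by loess in limma 3.58.1 under R 4.3.3, with control and outlier-marked spots at weight 0. Spots of a probe were averaged as log2 of embryo over reference. Probes were kept where they were well above background in Cy3 on both arrays of at least 1 group, which left 23444 of 42006. The spread was estimated over all 8 arrays by lmFit and eBayes (4 residual and 3.01 prior degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method at 0.05. The groups shared a common spread per probe, although the log2 difference of replicates varied more in Cnr1-null blastocysts (SD 0.815) than in wild type (0.4) or Faah-null blastocysts (0.382). A common spread tends to give too many calls for a noisier group and too few for quieter ones. All tests were two-sided. The small number of arrays limits the precision. Values per group are means with SD (n = 2), and errors of differences are standard errors from the fit. Where a probe was not well above background on either array of a group, the fold of the ratios is given beside a bound from the Cy3 channel. The bound sets the mean log2 Cy3 intensity of the brighter group, after loess and Aquantile scaling, against the higher of the dim probe's own value and the lowest value among probes well above background on the same array. Such bounds are open to dye bias, since the dyes were not swapped, and can exceed the fold of the ratios because they use the Cy3 channel alone. They are therefore not lower bounds on the fold of the ratios, to which the adjusted p-values belong.

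Wild type and Cnr1-null blastocysts lay on slide 1, and Cnr1-null morulae and Faah-null blastocysts on slide 2. Cnr1-null against wild type blastocysts and morulae against Faah-null blastocysts were thus compared within a slide. The other comparisons crossed slides, and among 23348 probes 6 parted slide 2 from slide 1 by at least 2-fold on every array. After the data were seen, 1617 probes that shared at least 20 bases were also joined into 730 families.

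The procedure was tested on simulated arrays of 23348 probes with each group's own spread and 200 changed probes per comparison. Each comparison was simulated once, with noise drawn independently for each probe. The shares of false calls thus hold for that number of changes and leave out deviations shared by many probes. For Cnr1-null against wild type blastocysts it recovered 5% of 2-fold and 55% of 4-fold changes, and 14.3% of its calls were false. For Faah-null against wild type the values were 1%, 45% and 4.17%. For Faah-null against Cnr1-null blastocysts they were 8%, 49% and 13.6%. For morulae against Cnr1-null blastocysts they were 9%, 59% and 32%, and for morulae against Faah-null blastocysts 5%, 57% and 1.59%. Alternatives covered the background correction, normalization, channel, filter, prior, array weights, threshold, the arrays in the fit, a replicate block and each array left out. With an array left out, the lone array of its group was assumed to vary like the other groups.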

Results

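Transcript levels were measured in day 4 mouse embryos that lacked the cannabinoid receptor CB1 (Cnr1-null), that lacked fatty acid amide hydrolase, the enzyme that degrades the endocannabinoid anandamide (Faah-null), or that were wild type. The study asked how lost or heightened endocannabinoid signalling alters the blastocyst, the stage that attaches to the uterus. Its design text left morulae, the preceding stage, out of its own expression analysis, but arrays of Cnr1-null morulae are among the 8 analysed here. Each of the 4 groups had 2 arrays, and the log2 ratios were read against the same reference RNA, while the Cy3 bounds used the embryo channel alone. Between 18532 and 24018 of the 42006 probes were well above background in the embryo channel of an array. The lowest number belonged to Cnr1-null blastocyst replicate 2, and the other 7 arrays had at least 21395. The files do not pair the probe identifiers with genes, so single probes are given with their sequences.

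Replicate arrays correlated across 23348 probes at r = 0.977 in wild type blastocysts, 0.978 in Faah-null blastocysts, 0.951 in Cnr1-null morulae and 0.900 in Cnr1-null blastocysts (probes are not independent replicates). The SD of the log2 difference between replicates was 0.400, 0.382, 0.595 and 0.815 in the same order. Cnr1-null blastocyst replicate 2 correlated at 0.844 to 0.900 with the other 7 arrays and stood apart on the first principal component, which held 34.7% of the variance. Counts without it are given for every comparison.

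**Figure D1:**
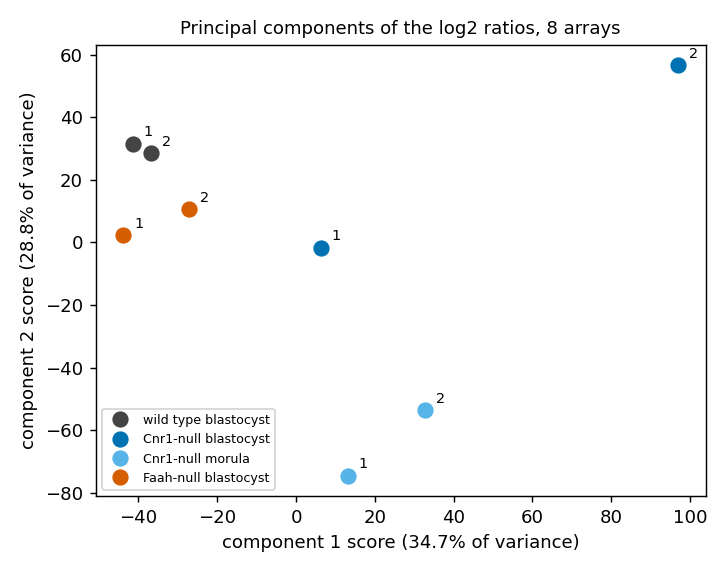
Scores of the 8 arrays on the first and second principal components of the log2 ratios of embryo over reference (34.7% and 28.8% of the variance); colours are the 4 groups and the digits are replicate numbers. Cnr1-null blastocyst replicate 2 lies at 96.9 on component 1, and the other arrays lie between -43.8 and 32.7.

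Loss of CB1 was addressed by the comparison of Cnr1-null with wild type blastocysts, which lay on the same slide. In the mutant, 67 probes were higher and 127 were lower, and the median size of these 194 differences was 2.28 on the log2 scale. At an unadjusted p under 0.05 the split ran the other way, with 2450 higher and 1682 lower. The median log2 difference of all probes was 0.085, and -0.081 with Agilent's processed signals. On both wild type arrays and neither mutant array 1403 probes were well above background, against 124 the other way. Among probes well above background on all arrays, 82 were called higher and 89 lower. Probe Z00039694-1 (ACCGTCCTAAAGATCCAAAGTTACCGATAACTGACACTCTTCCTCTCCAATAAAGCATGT) rose 20.9-fold, from a log2 ratio of 1.04 ± 0.27 (SD, n = 2) in wild type to 5.42 ± 0.18 in Cnr1-null blastocysts (adjusted p = 0.00445). Z00070062-1 (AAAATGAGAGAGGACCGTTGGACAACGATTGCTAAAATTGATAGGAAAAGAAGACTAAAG) rose 20.1-fold, with a wide spread in the mutant (5.34 ± 1.42 against 1.01 ± 0.31). The largest fall was that of Z00026697-1 (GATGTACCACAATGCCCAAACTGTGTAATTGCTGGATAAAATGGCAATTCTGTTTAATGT), from 6.37 ± 0.45 to 0.38 ± 0.92, and only 1 of the 2 mutant arrays measured it above background. Its log2 difference of -5.99 became -8.54 with Agilent's processed signals and with the authors' values, where its call was lost (adjusted p = 0.079 and 0.0801). The authors' values are no separate check, since both gave the same differences at the named probes they share. Z00026519-1 (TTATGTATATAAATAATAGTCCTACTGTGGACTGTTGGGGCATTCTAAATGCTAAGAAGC) was well above background on both wild type arrays and on neither mutant array. It was 29.3-fold lower by the ratios (adjusted p = 0.0064) and 35.7-fold lower by the Cy3 bound. In each of the 11 families with at least 2 called members, these moved in the same direction. This adds no independent support, since probes that share sequence can bind the same transcripts.

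The 194 calls rested on the spread shared by all 8 arrays. Within slide 1 alone, limma called 0 probes, with 2703 at an unadjusted p under 0.05. Without wild type replicate 1 the count was 11, without wild type replicate 2 it was 0 (2412 at an unadjusted p under 0.05), without Cnr1-null replicate 1 it was 5586 and without Cnr1-null replicate 2 it was 151. Without either morula array it was 84, and without either Faah-null array 54. Without wild type replicate 2 the adjusted p of the 4 named probes was 0.0773 to 0.151. Without wild type replicate 1 it was 0.243 for Z00070062-1, 0.0858 for Z00026697-1 and 0.0754 for Z00026519-1. Z00070062-1 also lost its call without either morula array (0.0636) or either Faah-null array (0.079). The excess of lower probes turned without Cnr1-null replicate 2 (83 higher, 68 lower), Cnr1-null replicate 1 (3781 and 1805) or wild type replicate 1 (8 and 3). Of the 151 calls without Cnr1-null replicate 2, 90 were among the 194.

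Loss of fatty acid amide hydrolase was addressed by the comparison of Faah-null with wild type blastocysts, and anandamide was not measured here. These lay on different slides, so slide and genotype were confounded. Differences fixed in the Faah-null line apart from the enzyme cannot be told apart from its loss. After the data were seen, 110 called probes measured on every array were checked by slide. Morulae lay on the Faah-null side of the midpoint at 59 of them, and Cnr1-null blastocysts on the wild type side at 56. A slide shift alone would put both so, which held at 11. In the mutant, 45 probes were higher and 67 lower, with a median size of 2.55 on the log2 scale. Z00057348-1 (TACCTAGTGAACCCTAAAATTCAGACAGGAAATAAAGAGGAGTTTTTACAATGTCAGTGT) stood at 7.17 ± 0.07 in wild type blastocysts and was not well above background on either Faah-null array. It was 123-fold lower there by the ratios (adjusted p = 0.00328) and 275-fold lower by the Cy3 bound. Z00012334-1 (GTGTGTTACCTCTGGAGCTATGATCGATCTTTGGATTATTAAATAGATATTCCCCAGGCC) fell in the same manner, 41.6-fold by the ratios (adjusted p = 0.000968) and 93.5-fold by the Cy3 bound. Z00027416-1 (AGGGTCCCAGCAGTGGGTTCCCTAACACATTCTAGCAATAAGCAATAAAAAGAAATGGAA) was not well above background in wild type blastocysts and stood at 2.26 ± 0.07 in Faah-null blastocysts. It was 46.5-fold higher there by the ratios (adjusted p = 0.003) and 63.8-fold by the Cy3 bound. Z00039694-1, which also rose in the Cnr1-null embryos, was 30.4-fold higher than in wild type (5.97 ± 0.02 against 1.04 ± 0.27, adjusted p = 0.00193).

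The count of 112 moved to 24 (15 higher, 9 lower) and 15 without wild type replicate 1 or 2, to 328 without either Cnr1-null blastocyst array, to 71 without either morula array, and to 9 and 19 without Faah-null replicate 1 or 2. With the 4 arrays of these groups alone it was 576, beside 0 for Cnr1-null against wild type fitted alone. The order of the counts 194 and 112 thus turned with the arrays that gave the spread. Without Faah-null replicate 1 the calls of Z00027416-1 (adjusted p = 0.054) and Z00057348-1 (adjusted p = 0.0593) ended, and without wild type replicate 2 that of Z00057348-1 did (adjusted p = 0.0544).

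**Figure D2:**
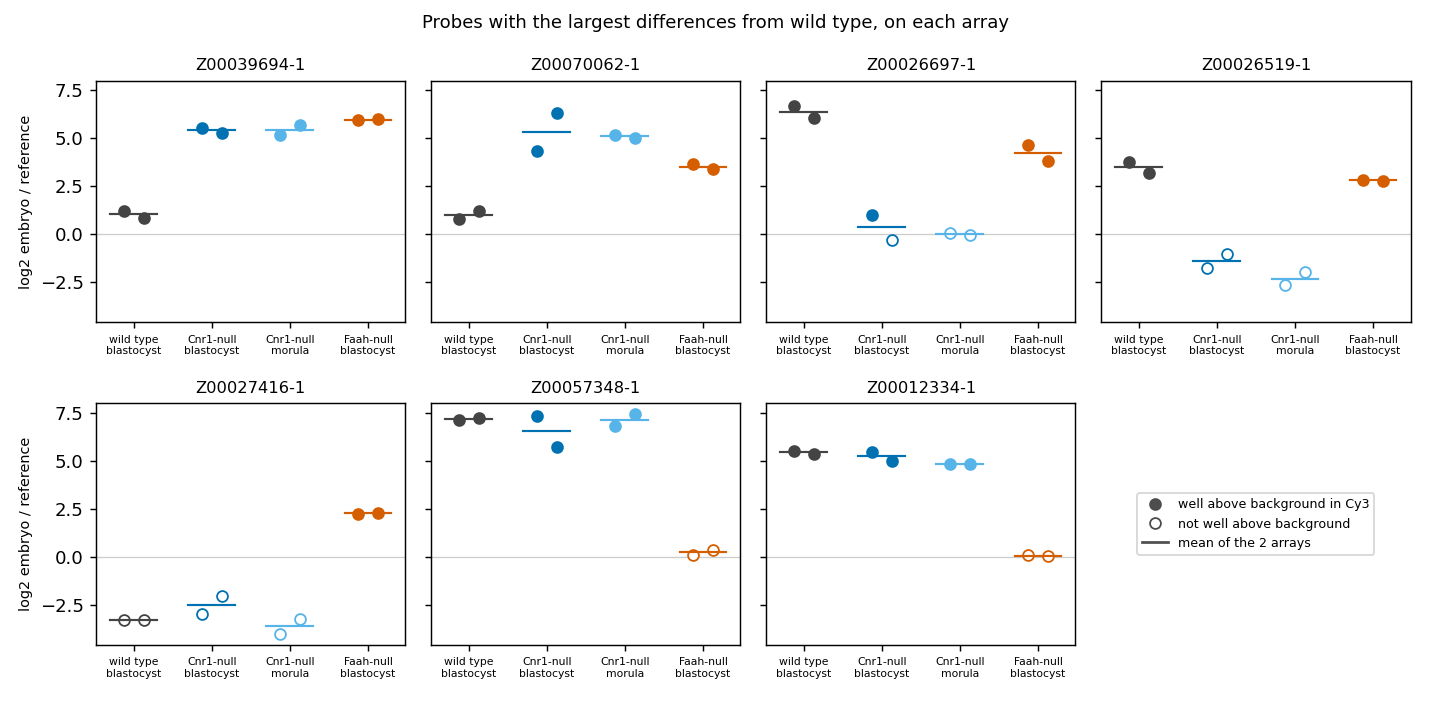
Log2 ratio of embryo over reference on each array (vertical axis) for the 7 probes with the largest rises and falls of either mutant against wild type, by group (horizontal axis). Filled points were well above background in Cy3, open points were not, and lines are means of the 2 arrays; Z00057348-1 lay at 0.11 and 0.35 on the Faah-null arrays and between 5.73 and 7.41 on the other 6.

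The mutants were compared for shared differences, since loss of the receptor and loss of the enzyme would alter endocannabinoid signalling in opposite senses. In all, 41 probes passed the threshold in the same direction in both, 16 higher and 25 lower, and 0 passed in opposite directions. Lists of these sizes drawn independently would share 0.129 higher and 0.363 lower probes, numbers that leave out the controls common to both. Z00039694-1 led the shared rises, followed by Z00050938-1 (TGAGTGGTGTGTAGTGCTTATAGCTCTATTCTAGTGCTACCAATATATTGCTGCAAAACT), which was 14.6-fold higher in Cnr1-null and 22.2-fold higher in Faah-null blastocysts (adjusted p = 0.019 and 0.0122). Among the shared falls, Z00035134-1 (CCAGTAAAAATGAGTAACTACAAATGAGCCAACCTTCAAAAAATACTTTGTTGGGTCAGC) was 19-fold lower in Cnr1-null and 19.9-fold lower in Faah-null blastocysts by the ratios (61.5-fold and 65.8-fold by the Cy3 bounds). Z00077422-1 (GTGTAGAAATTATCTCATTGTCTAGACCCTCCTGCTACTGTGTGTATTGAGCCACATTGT) was 12.2-fold and 15.2-fold lower. Across all probes the log2 differences correlated at r = 0.411, beside 0.261 simulated for unchanged groups with the shared controls. The covariance was 0.149 beside 0.0308 simulated. With each mutant set against a different wild type array, the differences correlated at 0.267 and 0.273. The split of shared probes into higher and lower turned to 19 and 9 with probes well above background on all arrays, 31 and 25 without Cnr1-null replicate 2, and 8 and 3 without wild type replicate 1. The number of shared probes was 56 without Cnr1-null replicate 2 and 166 without Cnr1-null replicate 1. It was 11 without wild type replicate 1, 0 without wild type replicate 2, 25 without either morula array, 4 without Faah-null replicate 1 and 7 without Faah-null replicate 2. Against wild type in Cnr1-null blastocysts, Z00039694-1, Z00035134-1 and Z00077422-1 lost the call without wild type replicate 2 (adjusted p = 0.0773) and with the arrays of these groups alone (0.105). Z00050938-1 lost it there without any 1 of the wild type, morula or Faah-null arrays (adjusted p = 0.0507 to 0.145), and in Faah-null blastocysts without any wild type or Faah-null array (0.0962 to 0.143).

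The difference between the mutant effects was tested by Faah-null against Cnr1-null blastocysts, again across slides. Here 87 probes were higher and 123 lower in Faah-null blastocysts. Z00027416-1 was 27.2-fold higher by the ratios (adjusted p = 0.00525) and 41.7-fold by the Cy3 bound, being not well above background in Cnr1-null as in wild type blastocysts. Z00023692-1 (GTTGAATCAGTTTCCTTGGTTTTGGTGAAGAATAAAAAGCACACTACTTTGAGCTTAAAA) was 23.5-fold higher by the ratios and 21.3-fold by the Cy3 bound. Z00057348-1 was 79.1-fold lower by the ratios and 320-fold by the Cy3 bound, as it was bright in Cnr1-null blastocysts (6.53 ± 1.13). Z00027010-1 (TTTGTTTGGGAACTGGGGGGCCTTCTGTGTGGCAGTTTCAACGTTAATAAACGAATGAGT) fell from 5.99 ± 0.02 to 0.78 ± 0.71, with 1 of 2 Faah-null arrays well above background (adjusted p = 0.00411).

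The direction of this count turned with Agilent's processed signals (68 higher, 46 lower) and with the authors' values (40 and 29), but not with median-centred arrays (80 and 124). The authors' values are no separate check, since both gave the same differences at the named probes they share. Agilent's signals also moved the median of all probes from -0.10 to 0.08 on the log2 scale. With the arrays of these groups alone limma called 0 probes (2895 at an unadjusted p under 0.05). The adjusted p of the 4 named probes was then 0.105 to 0.123. The 210 calls became 40 without either wild type array, 5775 without Cnr1-null replicate 1, 110 without Cnr1-null replicate 2, 63 without either morula array, and 4 and 5 without Faah-null replicate 1 or 2. Only Z00027010-1 of the 4 named probes stayed past the threshold without each Faah-null array, and the adjusted p of the other 3 was 0.073 to 0.078 without replicate 1 and 0.0603 to 0.0615 without replicate 2.

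**Figure D3:**
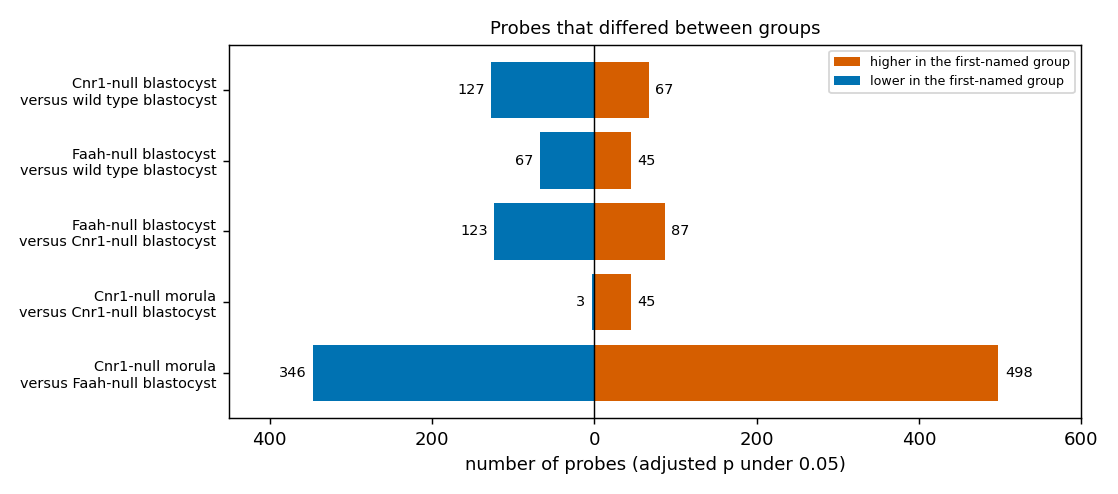
Number of probes past an adjusted p of 0.05 in each of the 5 comparisons (horizontal axis), to the right where the first-named group was higher and to the left where it was lower. The morula against Faah-null comparison had 498 higher and 346 lower, and the morula against Cnr1-null blastocyst comparison 45 and 3.

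Stage within one genotype was addressed by Cnr1-null morulae against Cnr1-null blastocysts, across slides. In morulae 45 probes were higher and 3 lower, while at an unadjusted p under 0.05 the split ran the other way, with 1879 higher and 2666 lower. The median log2 difference of all probes was -0.085, and 0.039 with Agilent's processed signals. On both morula arrays and neither blastocyst array 1630 probes were well above background, against 44 the other way. Among probes well above background on all arrays, 1 was called. Z00054262-1 (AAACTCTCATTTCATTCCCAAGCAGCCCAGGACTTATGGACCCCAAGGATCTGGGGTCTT) was at 5.71 ± 0.23 in morulae and 0.28 ± 1.48 in blastocysts, where 1 of 2 arrays was well above background (adjusted p = 0.0465). Z00054259-1 (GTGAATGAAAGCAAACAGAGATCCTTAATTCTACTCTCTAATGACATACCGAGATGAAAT) was at 5.53 ± 0.77 and 0.68 ± 0.82, again with 1 of 2 blastocyst arrays above background. Z00076378-1 (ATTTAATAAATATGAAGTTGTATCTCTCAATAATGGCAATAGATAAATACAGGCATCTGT) was 5.57-fold lower in morulae, and Z00026300-1 (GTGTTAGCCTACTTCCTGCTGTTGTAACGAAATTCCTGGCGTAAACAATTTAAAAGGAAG) 4.13-fold lower.

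These 48 calls were the least firm. In simulated arrays of this comparison 32% of calls were false, and limma called 0 probes with the 4 arrays of these groups alone (2037 at an unadjusted p under 0.05). Without Cnr1-null blastocyst replicate 2 the count was 13 (6 higher, 7 lower), of which 4 were among the 48, and without replicate 1 it was 5283 (1761 higher, 3522 lower), so the excess of higher probes was lost without either array. It was 0 without either wild type array (3387 at an unadjusted p under 0.05) or either Faah-null array (3408), and 12 without morula replicate 1. All 4 named probes lost their call without any 1 of the wild type, morula or Faah-null arrays, with an adjusted p of 0.0875 to 0.132. Without Cnr1-null blastocyst replicate 2 all but Z00054262-1 lost it (0.0692 to 0.0935).

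Cnr1-null morulae and Faah-null blastocysts lay on slide 2 and differed in both stage and genotype. This comparison gave 498 probes higher and 346 lower in morulae, with a median size of 1.78 on the log2 scale. Z00057348-1 was 119-fold higher in morulae by the ratios (7.12 ± 0.41, adjusted p = 0.00397), close to its wild type level, and 262-fold by the Cy3 bound. Z00031460-1 (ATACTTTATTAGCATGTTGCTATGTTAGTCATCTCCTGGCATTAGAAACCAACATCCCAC) stood at 6.04 ± 0.28 against 0.54 ± 1.03 (adjusted p = 0.023), with 1 of 2 Faah-null arrays well above background. Z00027416-1 was 58.7-fold lower by the ratios (adjusted p = 0.00308) and 78.3-fold by the Cy3 bound. Z00036567-1 (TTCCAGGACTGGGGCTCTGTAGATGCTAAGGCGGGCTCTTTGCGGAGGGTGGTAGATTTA) fell to 0.10 ± 0.17 from 5.29 ± 0.01 (adjusted p = 0.0403), with 1 of 2 morula arrays well above background. In each of the 40 families with at least 2 called members, these moved in the same direction, which is again no independent support.

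Within slide 2 alone, 565 probes were higher and 364 lower. The 844 calls became 512 with Agilent's processed signals. Leaving out arrays gave 314 without either wild type array, 2144 without either Cnr1-null blastocyst array, 210 and 218 without morula replicate 1 or 2, and 10 and 44 without Faah-null replicate 1 or 2. The call of Z00027416-1 held in all 8 of these fits (highest adjusted p 0.0465), and that of Z00057348-1 ended without Faah-null replicate 1 (adjusted p = 0.0556). Z00031460-1 and Z00036567-1 lost theirs without any 1 of the wild type, morula or Faah-null arrays (adjusted p = 0.0532 to 0.141 and 0.084 to 0.23).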

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

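The tests in this part were chosen after the result was seen, except that of signal brightness and the share of probes first used to test a wrong label for Cnr1-null blastocyst replicate 2.

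The effects of the mutations, each against the same wild type blastocysts, differed from each other at 210 probes by the direct comparison of Faah-null with Cnr1-null blastocysts (87 higher, 123 lower). With the arrays of these groups alone limma called 0 probes (2895 at an unadjusted p under 0.05). The split turned with Agilent's processed signals (68 higher, 46 lower). It also turned with the authors' values (40 and 29), which are no separate check, since both gave the same differences at the named probes they share. The groups lay on different slides. Cnr1-null morulae, which shared the slide of the Faah-null blastocysts, lay on the Faah-null side of the midpoint at 20 of the 209 probes measured on every array, and wild type lay on the side of the Cnr1-null blastocysts, its slide mates, at 87. A shift between slides alone would put both so, which held at 7.

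Probes called in Cnr1-null blastocysts tended to differ the same way in Cnr1-null morulae, although the 2 comparisons shared no array. Of the 194 calls, 81 were also called in the same direction between morulae and Faah-null blastocysts (23 higher, 58 lower) and 4 in the opposite one, where independent lists would share 1.42 higher and 1.87 lower, numbers that leave out the spread estimate common to both. An effect of array position argues for a negative correlation, since the contrasts lay in opposite positions on their slides, and the observed r was 0.310. With Cnr1-null blastocyst replicate 1 alone it was 0.335, which argues against the apart array as the source. Still open are a stage lag of Cnr1-null blastocysts (the correlation that it would raise was 0.0506 and 0.014), differences fixed in the Cnr1-null line apart from the receptor, which these 81 probes from 1 line cannot be told apart from, and an effect of the receptor itself, which was not tested.

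Cnr1-null blastocyst replicate 2 stood apart from its replicate and from all other arrays. In the 5837 probes brightest by the mean of both channels, the SD of the replicate difference was 0.673, against at most 0.417 in the other groups. Noise of probes dim in both channels may thus add to this but is not the whole of it. Probes dim in Cy3 but bright in the reference can be among the 5837, so noise of dim Cy3 signal is not excluded. That SD does not say which of the 2 arrays deviates. Replicate 1 had the highest median CV of repeated spots, 13.43% against 6.71% in replicate 2 and at most 9.16% in the other groups. This CV rests on only 7 probes with 5 spots each. Across all probes, replicate 1 correlated at 0.927 to 0.953 with the arrays of other groups, and replicate 2 at 0.844 to 0.882. The Cy5 channel of replicate 2 read 3.62% of the Cy3 signal at 26 probes bright only in embryos, against at most 0.726% on the other arrays. Yet the Cy3 channel alone still gave a replicate correlation of 0.945 against at least 0.978 elsewhere. Of 191 probes that parted the other 3 Cnr1-null arrays from wild type and Faah-null arrays, 74.3% lay on the Cnr1-null side here, below the 80% set in advance to exclude a wrong label, but wild type and Faah-null arrays left out in the same manner had at most 11.9%, which argues against a whole sample of either (the morula arrays had 88.1% and 91.6%, and Cnr1-null blastocyst replicate 1 had 43.1%, where the morulae alone stood for the Cnr1-null side). Still open, as untested, are a mixed sample, another sample from outside these groups, the quality of the RNA, uneven amplification and a difference between the embryo pools.

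Both mutants differed from wild type blastocysts in the same direction at 41 probes. Chance values of the shared wild type arrays do not account for all of it, since the covariance was 0.149 against 0.0308 simulated, and differences taken against separate wild type arrays still correlated at 0.267 and 0.273. A peculiarity of the 2 wild type pools cannot be told apart from an effect common to the mutants, since no other wild type sample was analysed here. The morulae lay on the mutants' side of the midpoint at 95% of the 40 shared probes measured on every array, as either would give.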

How the results depend on the processing

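Most counts depended on the processing, and apart from values on the probes of the authors' table, chosen after seeing the data, these alternatives were chosen before the data were examined. The cause of each move below was not tested. Probe counts are given in the order Cnr1-null against wild type, Faah-null against wild type, Faah-null against Cnr1-null, morulae against Cnr1-null blastocysts, morulae against Faah-null blastocysts, and shared by both mutants, and stood at 194, 112, 210, 48, 844 and 41. Aquantile scaling leaves the ratios unchanged, and the smallest called difference (0.89 on the log2 scale) already passed a 1.5-fold minimum, so neither could move a count. A normexp offset of 10 and a trended robust prior kept each within 1.5 times. The authors' values gave 101, 60, 69, 92, 394 and 23, over fewer probes. The scanner values on the same probes gave 147, 70, 172, 64, 675 and 27, so the smaller set of probes does not account for the whole move. Array weights gave 32, 2343, 31, 0 (limma, 2021 at an unadjusted p under 0.05), 2018 and 21. Both arrays of a group received the same weight, from 0.309 in Cnr1-null blastocysts to 2.06 in Faah-null blastocysts. This setting thus did not weight Cnr1-null blastocyst replicate 2 apart from replicate 1. A threshold of 0.01 gave 19, 23, 29, 0 (limma, 4545 at an unadjusted p under 0.05), 89 and 7, and one of 0.10 gave 554, 271, 485, 348, 1872 and 104. With the arrays of the compared groups alone limma gave 0, 576, 0 and 0 for the first 4, with 2703, 2895 and 2037 probes at an unadjusted p under 0.05 beside the zeros, and within slide 1 alone the first was 0 (2703). Agilent's processed signals gave 114 (68 higher, 46 lower, against 87 and 123), 131 and 512 for the last 3 comparisons, and moved the median log2 difference of all probes in the first from 0.085 to -0.081. Without the filter the third was 100 and the fourth 2. The fourth was 5 with the Cy3 channel alone, 15 with median-centred arrays and 1 with probes well above background on all arrays. Leaving out 1 array at a time gave 0 to 5586, 9 to 328, 4 to 5775, 0 to 5283, 10 to 2144 and 0 to 166. The correlation of the mutant effects ran from 0.289 to 0.511 in these fits and was 0.546 over probes called in either mutant. The labels tie replicate numbers to no shared animal or batch, and same-numbered deviations correlated at -0.04 to 0.24 across probes over 2 pairs. The replicate block gave 11 for morulae against Cnr1-null blastocysts and 830 for morulae against Faah-null blastocysts, and of the named probes only the 4 of the former passed the threshold no longer (adjusted p = 0.0619 to 0.0648). No named probe reversed, and they stayed past the threshold in 136 of 208 results without 1 array and in 233 of 292 under the other settings that could end a call. A mean over the probes of a gene and the gene list tests were not run, as the probes have no gene names here. For probes not well above background, the dim signal limits both the fold of the ratios and the Cy3 bound.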

Other observations

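The tests in this part were chosen after the data were seen. The largest family of related probes, 23 members of which 16 share the stretch ACCTGCAGAAAGGGTCATTT, parted morulae from Faah-null blastocysts. All 23 were higher in Cnr1-null morulae than in Faah-null blastocysts, by 0.54 to 2.92 on the log2 scale (median 1.93), and 15 passed the threshold. The direction of all 23 held with the Cy3 channel alone, with Agilent's processed signals and with median-centred arrays, where 11, 6 and 14 passed. The median was 1.52, 3.64 and 1.91 in the same order. Faah-null blastocysts were also lower than Cnr1-null blastocysts at 21 of the 23 probes (median -1.84), of which 5 passed, against 2 without Cnr1-null blastocyst replicate 2, 2 with the Cy3 channel alone and 1 with Agilent's processed signals. With Agilent's processed signals the median of -1.84 became -3.37. The median of the family was 0.17 and 0.85 on the wild type arrays, 0.87 and 1.80 on the Cnr1-null blastocyst arrays, 1.71 and 1.49 on the morula arrays, and -0.31 and -0.63 on the Faah-null arrays. Against wild type, 0 members passed in either mutant in limma's fit of all arrays, and 1 was higher in Cnr1-null blastocysts without their replicate 2 and 1 with Agilent's processed signals. Probes that share sequence can bind the same transcripts, so the members are not independent measurements.

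Counting probes that separated whole sets of arrays by at least 2-fold gave the groups' own marks among 23348 probes. Cnr1-null morulae stood apart from all other arrays at 182 probes (144 higher, 38 lower), wild type blastocysts at 107 (60 and 47), Faah-null blastocysts at 101 (28 and 73) and Cnr1-null blastocysts at 17 (9 and 8). The 4 Cnr1-null arrays, of both stages and on different slides, were parted from wild type and Faah-null arrays at 126 probes (61 and 65). The same number of arrays parted by slide gave 6 probes, and Cnr1-null and Faah-null blastocysts against wild type and morulae gave 4. Without Cnr1-null blastocyst replicate 2 these 3 counts were 191, 13 and 10, and with the Cy3 channel alone they were 160, 2 and 3. The counts of single groups depended on that array too: without it they were 301 for morulae, 154 for wild type, 129 for Faah-null and 80 for Cnr1-null blastocysts, and with the Cy3 channel alone 219, 119, 122 and 8. At a gap of at least 4-fold, Faah-null blastocysts stood apart at 31 probes, 25 of them lower. Morulae did so at 21, wild type at 19 and Cnr1-null blastocysts at 2. The 4 Cnr1-null arrays were parted from wild type and Faah-null arrays at 16.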
